A study of Homo sapiens with 7 samples.

How the data were processed

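RNA was measured in H4 cells, an established human neuroglioma line, that carry opto-PKR. Opto-PKR joins the light-clustering protein Cry2Olig to PKR, a kinase (gene EIF2AK2) that phosphorylates the translation factor eIF2 and so starts the integrated stress response (ISR). Per the labels, cells in a glass-bottom plate were kept under continuous blue light for 0, 60, 120, 240, 480, 600 or 720 min and lysed at once, and 1 library was made per time with an adaptation of CEL-Seq2, a method that counts the 3' ends of transcripts with unique molecular identifiers (UMIs). The 7 libraries are therefore 7 groups of 1 sample each. An unlit culture at the later times and lit cells without opto-PKR were not analysed here, so illumination and time in the plate move together.

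For each library the authors deposited 3 gene tables of expected counts (values that need not be whole): reads, UMIs and transcripts, each with 96 barcode columns, and a short mapping summary with read totals. The submitters' processing notes name BWA and the genome build hg19; their versions, the annotation and the counting program are not given in the sources used here. The deposited transcript counts equal the UMI counts corrected for UMI collisions with 4096 possible UMIs (largest difference 7.4e-10), and 81.5% of the deposited UMI counts were whole within a tolerance of 1e-06. How reads that match several genes were counted is not given in the sources used here, so genes with near-identical copies, such as ribosomal protein genes, are uncertain. Gene symbols and chromosomes are those of the row names; the reference in hand is of another build, so no coordinates are given.

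The column of barcode 4, the primer the labels name, was used, and the transcript counts were rounded to whole numbers. The 6 complete tables hold 7048253 to 8911818 transcripts and 11637813 to 15859529 reads in genes, and between 2.08 and 2.38 reads per UMI. The table of the 480 min library stops at the gene NME1-NME2 in alphabetical order and holds 5266123 transcripts. It lists 9854 genes, against 16543 to 17064 in the others. Genes named after that point were treated as missing at 480 min, not as 0. Of the genes at 10 or more transcripts in the 6 complete tables and named up to that point, 0 were missing at 480 min, so a gene absent within the range was taken as 0. Between 17 and 42 genes per library had over 3800 UMIs, where the collision correction is steep and levels are imprecise. ERCC spike-in RNA names no gene and was left out of library sizes and tests and held 0.00596% to 0.0124% of the gene reads in the complete tables.

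Genes with at least 10 counts in at least 3 libraries were tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood F test). Normalization was TMM over the 6 complete libraries, and the 480 min library was scaled to them over the genes it lists. Genes up to the end of that table were fitted on 7 libraries and later genes on 6, and all p-values were adjusted together (Benjamini-Hochberg, threshold 0.05). The design had been written for 7 libraries throughout, and the division into 2 parts was chosen after the table was seen to be incomplete. The trend is the slope on minutes, given as the fitted log2 change from 0 to 720 min, with 5 residual degrees of freedom (4 for later genes). The curve is the quadratic coefficient, with 4 (or 3). It is given as a bend: the fitted level at 360 min minus the mean of the fitted levels at 0 and 720 min, in log2. That scale was chosen after the first fit and does not alter the test. Residual spread includes both noise and departure from the fitted shape, since no time was repeated, and it may be technical. Levels are CPM (counts scaled to the effective library size).

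Single times were compared with 0 min without a test, as log2 ratios with a prior count of 2, with exact binomial 95% intervals that cover counting error only. The intervals, and the values given as folds, come from the counts without the prior. They take the collision-corrected counts as plain counts. For abundant genes such as HSPA5 the intervals therefore cover only part of the counting error. At low counts the prior draws a log2 ratio towards 0 within its interval. Genes with at least 50 counts in either library were counted as different at 2-fold. A gene at 0 counts at 0 min was set to a floor of 3 counts in that library. The median of each gene list was ranked among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries.

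A set of 23 gene lists with 517 symbols was fixed before the data were examined. Lists were tested for the slope with limma 3.58.1 (camera statistic, preset correlation 0.01). Because values are missing at 480 min, the statistic was taken from moderated statistics fitted in the same 2 parts, a change from the design. Camera with an estimated correlation and fry, a rotation test, were run on the 6 complete libraries. List means were also correlated with minutes over all 5040 orders of the 7 times (exact permutation, two-sided), for which the smallest possible p is 4e-04. The mean at 480 min is over the members that table lists, each centred on its mean in the 6 complete libraries. Of the 13 mitochondrially encoded genes of 1 list 0 were measured, so 22 lists were tested.

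The named genes follow a rule fixed before the data were examined. It takes the 12 rising and 12 falling genes of largest fitted change with a mean of at least 20 counts, and the 5 genes of smallest p for each sign of the bend. It adds 11 core genes, up to 4 called members per list (otherwise the 2 most abundant) and, per time, the 3 largest increases and 3 largest decreases from 0 min. Other genes are named only in the closing section or where said. One result for a gene the rule selects is not reported here.

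The scripts were tested on simulated counts with the real means and library sizes and a dispersion of 0.05. For the trend over 13437 genes, 90.9% of the genes given a log2 change of 2 were recovered, and 15.0% of those given 1. For the curve over 13457 genes, the shares were 83.0% and 12.0%. False calls were 4 and 2. The simulated changes followed the fitted line or curve exactly, so recovery was not measured for genes whose course departs from that shape. In the simulation of 22 lists, 1 raised list was called with 0 others, and 0 lists were called when none was raised. Genes were simulated independently of each other. In the data the estimated correlation within a list was 0.31 for ISR regulators and 0.78 for cytosolic ribosomal proteins. The simulation therefore does not show how often the preset correlation of 0.01 gives false list calls in these data.

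The alternatives fixed before the data were examined were UMI or read counts, RLE size factors, other count filters, leaving out each time, thinning to equal depth, other time scales, late against early times, a spline, DESeq2 1.42.0, the sum of all barcode columns and a prior count of 0.5. No other setting was added.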

Results

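The data trace the transcriptome of opto-PKR H4 cells over 720 min of continuous blue light, with the aim, per the study's design text, of following the ISR over time. There was 1 library at each of 7 times, so no value below has a replicate, and intervals cover at most counting error. Gene counts summed to 8.50e+06 transcripts at 0 min, 7.05e+06 at 60 min, 7.57e+06 at 120 min, 8.91e+06 at 240 min, 8.88e+06 at 600 min and 7.92e+06 at 720 min. The table at 480 min, incomplete after the gene NME1-NME2, held 5.27e+06.

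The first question was how far each time stood from the unlit library. After 60 min the immediate early transcription factors led: EGR2 went from 11 to 200 counts (log2 ratio 4.2, 95% interval 3.56 to 5.46), EGR1 was higher by 3.36 (3.17 to 3.58) and FOS by 3.06 (2.63 to 3.66). At 120 min EGR2 stood at 5.18 (4.57 to 6.44) and the cytokine IL6 at 4.02 (3.67 to 4.51). At 240 min IL6 reached 272 CPM from 6.12 CPM, a log2 ratio of 5.42 (5.08 to 5.90), followed by the cytokine IL24 at 4.12 (3.58 to 5.03). The hair keratin-associated gene KRTAP4-8 went from 3 counts to 52 at 120 min (3.54, interval 2.61 to 6.56) and 87 at 240 min (4.06, 3.17 to 7.07). It belongs to a family of similar genes. From 480 min the largest ratios belonged to other genes: the splicing regulator ESRP1 at 6.42 (5.65 to 8.89) at 480 min, among the genes listed there, and the cornified envelope gene SPRR2D at 7.36 (6.76 to 8.61) at 600 min and 8.33 (7.73 to 9.58) at 720 min.

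Losses were smaller at first. PPOX, a haem synthesis enzyme, was lower by a log2 ratio of -1.55 (-2.58 to -0.811) at 60 min, CNFN at -1.52 and LOC100506100 at -1.43. At 120 min MED18, a Mediator subunit, stood at -3.28 (-5.12 to -2.45), the coagulation factor gene F5 at -2.45 and ASTN2 at -2.14. At 240 min EFNA2 stood at -3.72 (-6.22 to -2.89), FLG2 at -3.23 and TMEM100 at -3.17. METTL7A, at -3.80 (-4.46 to -3.38), was lowest among the genes listed at 480 min, with CBLN2 and METTL7B both at -3.52. The gene PI15 was lowest at 600 min, at -4.41 (-5.33 to -3.89), and at 720 min, at -5.40 (-7.05 to -4.67). Shares were first taken over genes named up to the end of the 480 min table, with at least 50 counts in either library. These were 6205 to 6467 genes, depending on the time. The share at least 2-fold from 0 min was 2.55% at 60 min, 8.72% at 120 min, 16.6% at 240 min, 15.7% at 480 min, 10.8% at 600 min and 10.0% at 720 min. Over all genes compared, 274, 945, 1876, 1014, 1200 and 1044 genes were at least 2-fold from 0 min, the 480 min count being over fewer genes. These are ratios of 2 libraries each and have no replicate check.

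**Figure D1:**
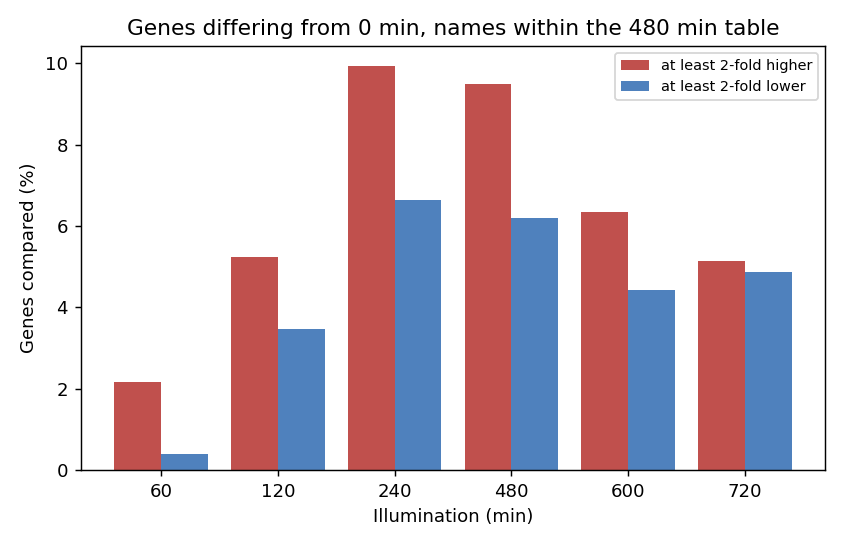
Percentage of genes (y axis, starting at 0) at least 2-fold higher (red) or lower (blue) than at 0 min, for each illumination time in minutes (x axis), over genes whose names lie within the 480 min table. The summed share is 2.55% at 60 min and 16.6% at 240 min, and 10.0% at 720 min; each bar compares 2 libraries.

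The core ISR transcripts were examined next. ATF4, the transcription factor at the centre of the response, rose from 311 CPM at 0 min to 620 CPM at 720 min, a fitted log2 change of 0.89 ± 0.16 (SE, edgeR adjusted p = 0.0156). TRIB3, a pseudokinase induced by ATF4, rose by 3.71 ± 0.33 (adjusted p = 0.0014), from 44.6 to 387 CPM. ASNS, asparagine synthetase, rose by 2.37 ± 0.25 (adjusted p = 0.00183), from 248 to 938 CPM, and SESN2, a stress-induced regulator of mTORC1, by 2.40 ± 0.59 (adjusted p = 0.0488). SESN2 also bent upward by 1.73 ± 0.21 (edgeR adjusted p = 0.000394), a call that held in all 14 alternatives. ATF3, a further stress transcription factor, showed an upward bend of 2.53 ± 0.59 (adjusted p = 0.0317), from 27.3 CPM at 0 min to 335 CPM at 240 min and 113 CPM at 720 min. DDIT3, which encodes CHOP, bent upward by 1.40 ± 0.37 (adjusted p = 0.026): 15.3 CPM at 0 min, 96.5 CPM at 240 min and 94.5 CPM at 720 min.

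Several core genes passed neither test although their levels differed from 0 min by more than counting error. PPP1R15A, the eIF2 phosphatase subunit GADD34, was 7.81-fold (7.07 to 8.65) the 0 min level at 240 min and 6.66-fold at 720 min. CHAC1, a glutathione-degrading enzyme, was 8.70-fold (7.87 to 9.65) at 240 min and 8.73-fold at 720 min, and DDIT4 4.00-fold and 4.22-fold. The ER chaperone gene HSPA5 was at 0.533 of its 0 min level at 240 min (0.511 to 0.556) and at 1.35 (1.3 to 1.39) at 720 min; its trend was 0.73 ± 0.31 (adjusted p = 0.194). EIF2AK2 itself bent downward by -1.06 ± 0.28 (adjusted p = 0.0178), from 188 CPM to 66 CPM at 240 min and 130 CPM at 720 min; these counts do not separate the native gene from the introduced fusion. Several of these calls were lost when 1 library was left out, and each lost call kept its direction. A gene with a value in that library is left with fewer degrees of freedom. SESN2 has no value at 480 min, so leaving out that library removed none of its values, and its fitted change stayed at 2.40. Without that library all genes were fitted together, not in separate parts. This alters the spread estimated across genes and the adjustment of p-values. ATF4 lost its trend without the library at 60 min (0.82, adjusted p = 0.0846) or 600 min (0.92, adjusted p = 0.0749), and SESN2 without that at 60, 120, 480, 600 or 720 min (2.21 to 3.21, adjusted p from 0.062 to 0.214). The DDIT3 bend was no longer called without 60 min (1.47, adjusted p = 0.0639) or 240 min (1.19, adjusted p = 0.18). That of ATF3 was not called without 240 min (2.38, adjusted p = 0.171), 600 min (2.59, adjusted p = 0.0535) or 720 min (3.37, adjusted p = 0.0618), although its size stayed near 2.53 or above. That of EIF2AK2 was not called without 0 min (-0.66, adjusted p = 0.0873) or 240 min (-0.83, adjusted p = 0.0916). PPP1R15A gained an upward bend without 600 min (2.30, adjusted p = 0.00432) or 720 min (2.98, adjusted p = 0.00137). HSPA5 gained a downward bend without 480 min (-1.05, adjusted p = 0.00282) or 720 min (-1.26, adjusted p = 0.014), and a rising trend without 0 min (1.13, adjusted p = 0.0328). Without 0 min TRIB3 and ASNS gained upward bends (1.21 and 0.79, adjusted p = 0.00537 and 0.004). Other settings mattered too. The SESN2 trend was lost with UMI counts, read counts, RLE size factors or a stricter count filter (adjusted p from 0.0514 to 0.0532), the ATF3 bend with UMI counts (0.06) or no count filter (0.0569) and the DDIT3 bend with no count filter (0.0504). On the rank time scale PPP1R15A (1.48, adjusted p = 0.00089) and CHAC1 (1.29, adjusted p = 0.0429) gained upward bends and HSPA5 a downward bend (-0.79, adjusted p = 0.0283), which it also gained with UMI counts (-0.50, adjusted p = 0.00642). DDIT3 gained a rising trend on the log time scale (2.37, adjusted p = 0.0194) and with DESeq2 (1.68, adjusted p = 0.0245).

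**Figure D2:**
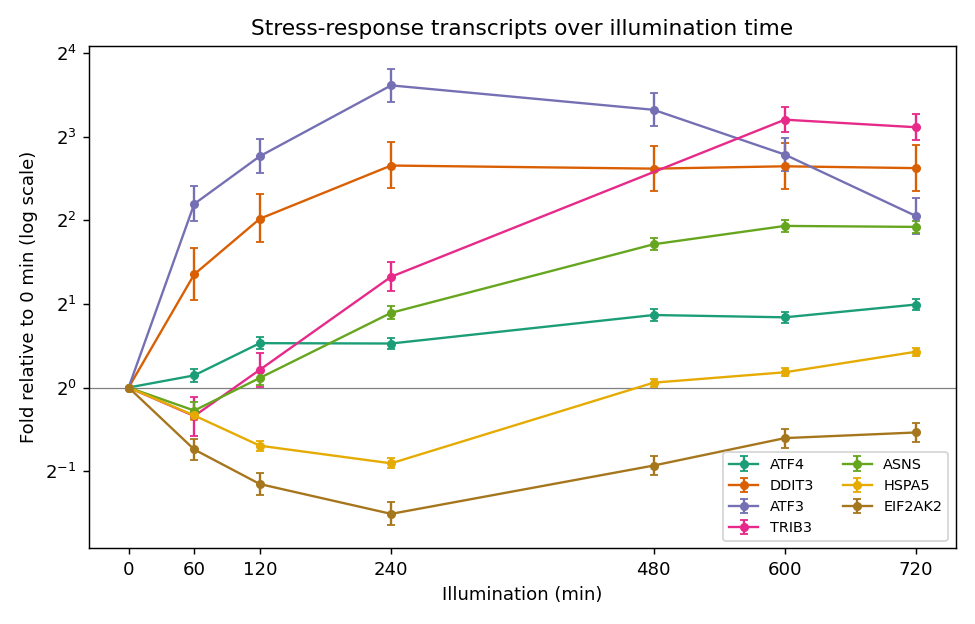
Fold relative to 0 min (y axis, log scale) against illumination time in minutes (x axis) for 7 core genes, 1 library per time; bars are exact binomial 95% intervals of counting error, and TRIB3 has no value at 480 min. ATF3 peaks at 240 min, TRIB3 and ASNS keep higher late levels, and HSPA5 and EIF2AK2 are lowest at 240 min. For abundant genes the bars cover only part of the counting error.

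Over all genes, 930 of 13566 had a trend, 529 rising and 401 falling, and 3129 had an unadjusted p under 0.05 (edgeR quasi-likelihood). SPRR2D rose most, by a fitted log2 change of 9.11 ± 0.29 (SE, adjusted p = 7.75e-06), from 11 counts at 0 min to 3741 at 720 min. ESRP1 rose by 7.28 ± 0.99 (adjusted p = 0.00485), from 4 to 433 counts. FGF21, a hormone gene known as an ATF4 target, had 0 counts at 0 and 60 min and 55 at 720 min, at least 16.2-fold higher (exact binomial 95% lower limit), or 20.6-fold the floor in the 0 min library. KLHDC7B went from 1 to 104 counts (117-fold, interval 20.5 to 4653), the dopamine receptor gene DRD5 from 3 to 163 (61-fold, 20.5 to 299), the dynein gene DNAH10 from 3 to 49 (18.3-fold, 5.91 to 91.9) and the transketolase-like gene TKTL1 from 2 to 65 (36.5-fold, 9.70 to 307). S100P, a calcium-binding protein gene, rose by 5.92 ± 0.36, SH3BGR by 4.82 ± 0.31, LOC100505633 by 4.63 ± 0.37, the activin subunit gene INHBE by 4.44 ± 0.87 and BEX2 by 4.40 ± 0.33.

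Of the falling genes, PI15, a secreted protease inhibitor, fell by 5.63 on the log2 scale (SE 0.309, adjusted p = 0.00013), from 48.9 to 0.925 CPM. METTL7A fell (-5.02 ± 0.313), TMEM100 (-5.05 ± 0.665), CBLN2 (-4.60 ± 0.493), LRRC17 (-4.57 ± 0.412) and OLFML2B (-3.86 ± 0.617). Others with a fitted fall stood above their 0 min level within the first 240 min. RGS1, a regulator of G protein signalling, (-4.56 ± 0.723) stood at 15.2 CPM at 0 min, 28.9 CPM at 60 min and 0.66 CPM at 720 min. FOS stood at 4.36 CPM at 0 min, 46.5 CPM at 120 min and 1.32 CPM at 720 min (adjusted p = 0.045), and EGR1 at 26.6, 276 at 60 min and 15.1 CPM (adjusted p = 0.0485). C10orf10 (17.7, 63.5 at 120 min and 2.77 CPM), the bradykinin receptor gene BDKRB2 (5.77, 21.5 at 120 min and 0.925 CPM) and LOC729950 (7.77, 9.38 at 240 min and 0.264 CPM) were likewise higher in between than at either end. The calls of 11 of the 12 rising genes held under every alternative that gave a value, INHBE being lost without 60, 120 or 600 min (adjusted p from 0.064 to 0.088). Of the 12 falling genes, PI15, METTL7A, CBLN2 and LRRC17 held. TMEM100 was lost without 600 min (adjusted p = 0.0649), OLFML2B without 60 or 600 min (0.0515 and 0.077) and RGS1 without 60, 600 or 720 min (0.0526 to 0.0774). EGR1 was lost without any 1 of the libraries from 60 to 720 min (0.0513 to 0.212), and FOS and BDKRB2 without 60, 120, 480, 600 or 720 min (0.0846 to 0.204). C10orf10 was lost without 60, 480, 600 or 720 min (0.0578 to 0.136) and LOC729950 without 120, 480, 600 or 720 min (0.0603 to 0.112). FOS, EGR1, BDKRB2, C10orf10 and LOC729950 were also lost on the log and rank time scales, and RGS1 on the log time scale. FOS, EGR1 and BDKRB2 were lost with no count filter. EGR1 and BDKRB2 were lost with UMI counts, RLE size factors or a stricter count filter, and BDKRB2 after thinning. The number of calls varied with the library left out: it was 1481 without 0 min, 282 without 60 min, 354 without 120 min, 135 without 600 min and 469 without 720 min, and 1581 with DESeq2.

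Bends were called more often than trends: 4238 of 13566 genes, 2379 upward and 1859 downward, and 149 genes had both calls. The numbers of bends and trends are not on equal terms. Curvature adds to the residual spread of the trend, while the curve fit includes the slope. The upward bend of smallest p was that of CYP1A1, a cytochrome P450 gene, at 3.08 ± 0.18 (SE, edgeR adjusted p = 5.05e-06): 8.71 CPM at 0 min, 108 CPM at 480 min and 24.4 CPM at 720 min. C9orf84 bent upward by 2.80 ± 0.24, AJUBA, a LIM-domain scaffold gene, by 1.85 ± 0.16, the zinc finger gene ZFY by 2.14 ± 0.21 and the integrin gene ITGB8 by 1.72 ± 0.17. The downward bend of smallest p was that of DBNDD1 at -1.91 ± 0.21, which went from 58.2 CPM to 10.3 CPM at 480 min and 26.4 CPM at 720 min. MARCKSL1 bent by -1.09 ± 0.13, the HSP90 co-chaperone gene CDC37 by -1.37 ± 0.16, UCKL1-AS1 by -2.14 ± 0.27 and the immune checkpoint gene CD276 by -1.65 ± 0.21. The 10 bends named here held under every alternative that gave a value. Of 1305 upward genes fitted on 7 libraries, 53.3% were highest at 240 min and 35.8% at 480 min. Of 1095 such downward genes, 49.9% were lowest at 240 min. The count of bends was 1933 without the 0 min library and 1320 without the 240 min library.

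Gene lists were compared over time. Of 19 ISR regulators 8 rose and 0 fell (12 rose when adjusted over the list alone), with a mean fitted change of 1.89. VLDLR, a lipoprotein receptor gene, rose by 2.80 ± 0.55 and NUPR1, a stress-induced chromatin protein gene, by 2.72 ± 0.23, beside TRIB3 and FGF21. Of 20 genes of amino acid synthesis and transport 16 rose (18 rose and 1 fell adjusted over the list alone), with a mean of 1.63; the glycine transporter gene SLC6A9 rose by 3.63 ± 0.35, the folate enzyme gene ALDH1L2 by 3.59 ± 0.45 and PSPH, of serine synthesis, by 2.29 ± 0.42. Of 20 cytosolic tRNA synthetases 9 rose (11 adjusted over the list alone), with a mean of 0.69, among them SARS by 1.56 ± 0.23, WARS by 1.47 ± 0.22, CARS by 1.39 ± 0.28 and GARS by 1.31 ± 0.28. Camera with the preset correlation gave adjusted p = 1.88e-10, 1.03e-15 and 3.79e-07 for these 3 lists; the adjusted p with an estimated correlation was 0.296, 0.204 and 0.317. Of 22 lists 13 were called with the preset correlation, 0 with the estimated one and 9 with fry. VLDLR, CARS and GARS lost their calls without the library at 60, 120 or 600 min (adjusted p from 0.0653 to 0.148), PSPH without 60, 120, 600 or 720 min (0.0587 to 0.107), SARS without 600 or 720 min (0.0713 and 0.0573) and WARS without 600 min (0.0713). SARS and WARS also lost theirs on the log time scale.

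List means at 480 min are over fewer members: 12 of 19 ISR regulators, 7 of 20 amino acid genes, 13 of 20 synthetases, 15 of 19 cholesterol genes and 14 of 20 replication genes. For the ISR regulators, the list mean followed minutes with Pearson r = 0.913 (exact permutation p = 0.00694, adjusted over 22 lists 0.0306) and Spearman rho = 1 (exact permutation p = 4e-04, the smallest possible), and r was 0.924 without the 600 and 720 min libraries. Their median log2 ratio to 0 min was 0.32 at 60 min, 0.97 at 120 min, 2.00 at 240 min, 1.53 at 480 min (12 members), 2.30 at 600 min and 2.07 at 720 min, above at least 99.99% of matched random lists each time. The amino acid genes started later: -0.03 at 60 min, where 52% of random lists were lower, then 0.31, 0.85, 1.76, 1.25 and 1.37 at 120, 240, 480 (7 members), 600 and 720 min. The synthetases stood at -0.20 at 60 min, 0.64 at 480 min (13 members), 0.63 at 600 min and 0.40 at 720 min. For the amino acid genes r was 0.928 (exact permutation p = 0.0103, adjusted 0.0378), rho 0.821 (exact permutation p = 0.0341, adjusted 0.0938) and r 0.99 without 600 and 720 min. For the synthetases r was 0.901 (exact permutation p = 0.0175, adjusted 0.0427), rho 0.75 (exact permutation p = 0.0663, adjusted 0.146) and r 0.912 without those libraries. By Pearson's r, 9 of the 22 lists passed after adjustment. The smallest adjusted p was that of the extracellular matrix list (r = -0.921, exact permutation p = 4e-04, adjusted 0.00873). Mitosis genes (r = -0.972, exact permutation p = 0.00119, adjusted 0.0102) also had a smaller adjusted p than the ISR regulators. At 480 min these means are over 12 of 19 and 16 of 20 members.

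Other lists with an upward call had fewer called members and did not all rise steadily. NRF2 targets had 3 of 16 rising (7 adjusted over the list alone; camera adjusted p = 0.000304, and adjusted p = 0.567 with an estimated correlation): HMOX1, haem oxygenase, by 2.62 ± 0.66, OSGIN1 by 1.53 ± 0.36 and GCLM, of glutathione synthesis, by 1.45 ± 0.29. In the same list 9 members bent downward: the median log2 ratio to 0 min was -0.38 at 120 min and -0.57 at 240 min, where 0 of 16 members stood above 0, and 0.47 at 600 min and 0.40 at 720 min. Autophagy genes had 3 of 14 rising (4 over the list alone; adjusted p = 0.00338, and adjusted p = 0.317 with an estimated correlation): MAP1LC3B by 1.71 ± 0.17, GABARAPL1 by 1.41 ± 0.28 and WIPI1 by 1.14 ± 0.21. The p53 targets were called (adjusted p = 0.0446, and adjusted p = 0.545 with an estimated correlation) with 0 of 14 members called; CDKN1A had a fitted change of 1.13 ± 0.36 and C12orf5 of 0.43 ± 0.18, and the median log2 ratio of the list was 0.41 at 600 min and 0.07 at 720 min. Cytosolic ribosomal proteins were called upward (mean 0.26, adjusted p = 8.24e-07, and adjusted p = 0.63 with an estimated correlation) with 0 of 79 members called; 33 bent downward. Their median log2 ratio to 0 min was -0.23 at 60 min, -0.20 at 120 min, -0.33 at 240 min and -0.05 at 600 min. Among the times with a median it was above 0 only at 720 min (0.14). At 480 min 1 of the 79 members has a value, so no median was taken there. RPS6 stood at 0.09 ± 0.15 and RPL9 at 0.24 ± 0.15. They average 15635 and 15615 transcripts per library, where UMIs are nearly exhausted, so their levels are imprecise and UMI counts can hardly show a change. Copies of these genes elsewhere in the genome add to the uncertainty. The ribosomal protein call was lost without 720 min (mean 0.06, adjusted p = 0.346), as RPL9 turned to -0.05, and the p53 call without 120, 480 or 600 min (means 0.36, 0.35 and 0.29, adjusted p = 0.062, 0.0692 and 0.168). CDKN1A gained a rising trend without 0 min (1.64, adjusted p = 0.0165) and late against early times (0.92, adjusted p = 0.017). HMOX1 and OSGIN1 lost their calls without 60, 120, 480, 600 or 720 min (adjusted p from 0.0559 to 0.305), WIPI1 without 60, 120, 600 or 720 min (0.0542 to 0.121), and GCLM and GABARAPL1 without 60, 120 or 600 min (0.0627 to 0.103). OSGIN1 has no value at 480 min, so leaving out that library removed none of its values. On the log and rank time scales HMOX1, OSGIN1, GCLM and WIPI1 were lost, and HMOX1 also with no count filter or a stricter one. The p53 call was also lost on the rank time scale, with no count filter or with a stricter one. With fry the NRF2, p53 and ribosomal protein lists were not called (adjusted p = 0.206, 0.164 and 0.27).

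In each of the 6 lists called downward, every member called for a trend over all genes fell. Cholesterol synthesis, DNA replication and mitosis genes are given first. Of 19 cholesterol genes 7 fell (11 adjusted over the list alone), with a mean of -0.87 (camera adjusted p = 1.52e-08, and adjusted p = 0.204 with an estimated correlation). INSIG1, a sterol sensor partner, fell (-2.55 ± 0.263), as did DHCR7 (-1.25 ± 0.264) and HMGCS1 (-1.03 ± 0.215). For this list r was -0.968 (exact permutation p = 0.00139, adjusted 0.0102), rho -1 (exact permutation p = 4e-04) and r -0.961 without 600 and 720 min. Of 20 DNA replication genes 7 fell (12 over the list alone), with a mean of -0.72 (adjusted p = 1.43e-08, and 0.204 as the adjusted p with an estimated correlation): the cyclin gene CCNE2 (-1.45 ± 0.243), the helicase genes MCM3 (-1.38 ± 0.172) and MCM4 (-1.23 ± 0.228), and GINS2 (-1.09 ± 0.266). Of 20 mitosis genes 3 fell (7 over the list alone; mean -0.39, adjusted p = 3.4e-05, and adjusted p = 0.204 with an estimated correlation): KIF20A (-1.22 ± 0.172), MKI67 (-0.63 ± 0.15) and CDK1 (-0.62 ± 0.142). The median log2 ratio of the replication genes was -0.10 at 120 min and -0.69 at 600 min; r was -0.961 (exact permutation p = 0.00298, adjusted 0.0164), rho -1 (exact permutation p = 4e-04) and r -0.968 without 600 and 720 min. DHCR7, MKI67 and CDK1 lost their calls without 60, 120, 480, 600 or 720 min (adjusted p from 0.054 to 0.175), HMGCS1 without 60, 120, 480 or 600 min (0.054 to 0.14), GINS2 without 0, 60, 120, 480 or 600 min (0.0683 to 0.183), MCM4 without 60 or 600 min (0.0624 and 0.092) and CCNE2 without 600 min (0.0636). HMGCS1, CDK1 and MKI67 were also lost on the log and rank time scales. MKI67 was lost with read counts, no count filter or late against early times.

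Heat shock genes had 4 of 13 falling (7 over the list alone; mean -0.63, adjusted p = 1.22e-05, and adjusted p = 0.423 with an estimated correlation): HSPH1 (-1.10 ± 0.155), DNAJA1 (-0.87 ± 0.187), HSP90AA1 (-0.62 ± 0.148) and HSPB1 (-0.54 ± 0.129). Extracellular matrix genes had 2 of 19 falling (7 falling and 1 rising over the list alone; mean -0.40, adjusted p = 0.000505, and adjusted p = 0.352 with an estimated correlation): COL3A1 (-1.96 ± 0.182) and COL6A1 (-0.92 ± 0.183). Immediate early genes were called downward (mean -1.11, adjusted p = 0.0379, and adjusted p = 0.685 with an estimated correlation) with FOS and EGR1 the 2 called of 20, but their median log2 ratio to 0 min was 1.65 at 60 min, 1.99 at 120 and 240 min, and 0.14 at 720 min. DNAJA1 lost its call without 60, 120, 480 or 600 min (adjusted p from 0.0504 to 0.142), HSPB1 without 60, 120, 480, 600 or 720 min (0.0771 to 0.16), HSP90AA1 without any 1 library other than 240 min (0.0701 to 0.134), and COL6A1 without 60, 120, 600 or 720 min (0.0561 to 0.0995). The calls of FOS and EGR1 were lost without 60, 120, 480, 600 or 720 min (0.0995 to 0.212), and that of EGR1 also without 240 min (0.0513). The immediate early call was lost without the library at 60, 120, 240, 480, 600 or 720 min, with mean changes of -0.77 to -1.07 and adjusted p from 0.0516 to 0.219. It was also lost on the rank time scale, with a stricter count filter and with fry (adjusted p = 0.529). The heat shock list was not called with fry (adjusted p = 0.0877). HSPB1 was also lost with UMI counts, no count filter, thinning and the log and rank time scales. HSP90AA1 was lost with UMI or read counts, and COL6A1 on the log and rank time scales.

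**Figure D3:**
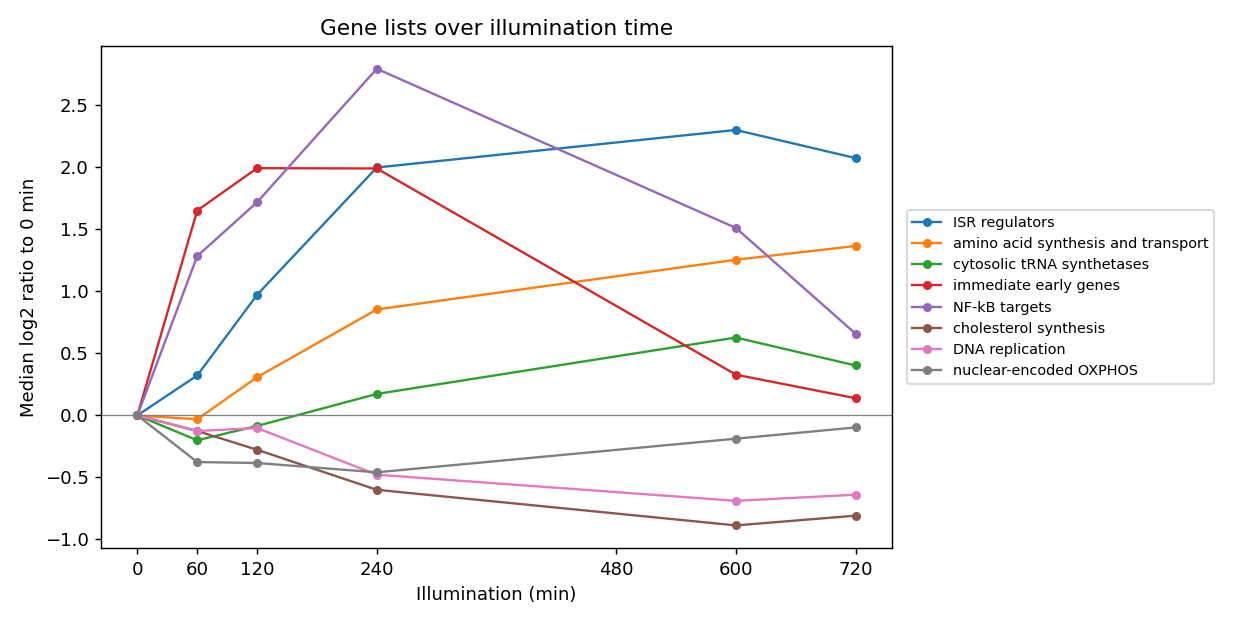
Median log2 ratio to 0 min (y axis) of 8 gene lists against illumination time in minutes (x axis); each point is the median over the measured members in 1 library, and the incomplete 480 min library is not drawn. ISR regulators stand at 2.00, 2.30 and 2.07 at 240, 600 and 720 min, immediate early genes return to 0.14 by 720 min, and cholesterol synthesis and DNA replication stay below 0.

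The remaining lists were not called for a trend with the preset correlation. NF-kB targets (camera adjusted p = 0.345) had 8 of 15 members bending upward and 1 rising (2 rising and 2 falling adjusted over the list alone), the chemokine gene CXCL3 by 3.53 ± 0.66; their median log2 ratio was 2.79 at 240 min and 0.66 at 720 min. Circadian clock genes (adjusted p = 0.856; mean and median just below 0 with an upward test statistic) had 11 of 16 bending upward, with a median of 1.3 at 240 min; BHLHE40 stood at 48.2 CPM at 0 min, 284 CPM at 240 min and 32 CPM at 720 min, and CLOCK had a fitted change of -0.08 ± 0.18. Nuclear-encoded OXPHOS genes (adjusted p = 0.371) had 19 of 51 bending downward and a median of -0.46 at 240 min; COX6A1 had a fitted change of 0.28 ± 0.16 and COX7C of -0.04 ± 0.14. ER chaperone and ERAD genes (adjusted p = 0.316) had 3 of 20 rising (4 adjusted over the list alone), DNAJB9 by 1.82 ± 0.29, the transcription factor gene XBP1 by 1.55 ± 0.28 and HERPUD1 by 1.22 ± 0.29, and 5 bending downward. Circadian and OXPHOS genes had 0 members called for a trend, over all genes or adjusted over the list alone. Single libraries set several of these values. Without 0 min the OXPHOS list was called upward (0.28, adjusted p = 0.000479), BHLHE40 had a falling trend (-3.79, adjusted p = 0.00798, and also late against early times) and the NF-kB mean was -0.51. Without 720 min the NF-kB list was called upward (1.03, adjusted p = 0.0336), the OXPHOS mean was -0.10 and CLOCK stood at 0.0072; the circadian mean was 0.05, 0.07 and 0.51 without 120, 240 and 720 min, and COX7C stood at 0.03 without 600 min. CXCL3 and XBP1 lost their calls without 60, 120 or 600 min (adjusted p from 0.0562 to 0.109), DNAJB9 without 600 min (0.0583), and HERPUD1 without any 1 library other than 240 min (0.0505 to 0.143).

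Apoptosis genes (adjusted p = 0.243) had 2 of 19 rising (2 rising and 1 falling adjusted over the list alone), the death receptor gene TNFRSF10B by 1.46 ± 0.24 and BCL2L1 by 0.83 ± 0.16. Interferon-stimulated genes (adjusted p = 0.243) had IFIT1 falling (-1.61 ± 0.191), IFI44 falling (-1.11 ± 0.195) and IRF7 rising by 1.28 ± 0.33 among 20 (2 rising and 4 falling adjusted over the list alone). Hypoxia and glycolysis genes (adjusted p = 0.472) had EGLN3 falling (-2.81 ± 0.355) and HK2 rising by 1.57 ± 0.40 among 20 (the same numbers, 1 and 1, adjusted over the list alone). Translation factors (adjusted p = 0.0627) had 1 of 23 rising (1 adjusted over the list alone), EIF4EBP1, a binding partner of eIF4E, by 2.02 ± 0.25, and the list was called upward without 0 min (0.25, adjusted p = 0.0365) and with read counts (0.28, adjusted p = 0.0283). Of the 18 markers of other cell types 4 were measured (adjusted p = 0.157); CD74 rose from 0.706 to 7.13 CPM, SYT1 rose by 0.84 ± 0.20 and SNAP25 fell (-3.02 ± 0.475). Adjusted over the list alone, 3 of these markers rose and 1 fell. Fry did call this list upward (adjusted p = 0.0318, and adjusted p = 0.398 with an estimated correlation in camera). Its mean, over 2 members at 480 min, followed minutes with r = 0.871 (exact permutation p = 0.0169, adjusted 0.0427), rho = 0.679 (exact permutation p = 0.11, adjusted 0.191) and r = 0.545 without 600 and 720 min. Its median log2 ratio was 0.53 at 600 min and 1.14 at 720 min, the latter above 99.6% of matched random lists. TNFRSF10B lost its call without 60 or 600 min (adjusted p = 0.0652 and 0.0957), BCL2L1 without 60, 120, 600 or 720 min (0.0543 to 0.127), IFI44 without 600 or 720 min (0.0713 and 0.0626), IRF7 without 0, 60, 120, 480 or 600 min (0.0752 to 0.221), HK2 and SYT1 without any 1 library other than 240 min (0.054 to 0.226) and SNAP25 without 720 min (0.0591). SYT1 has no value at 480 min, so leaving out that library removed none of its values. IRF7, SYT1 and HK2 were also lost with UMI counts, IRF7 and SYT1 with no count filter, and SYT1 and HK2 with read counts. HK2 was lost with RLE size factors or a stricter count filter, and BCL2L1 late against early times. Of the 13 mitochondrially encoded mRNAs 0 were measured.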

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

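The tests of the 480 min table and of keratinocyte genes were chosen after the results they bear on had been seen. Signals lay outside the values used for the comparisons. ERCC spike-in RNA, which names no gene, had 1867 reads at 0 min, 1013 at 60 min, 1021 at 120 min, 1189 at 240 min, 938 at 600 min and 1099 at 720 min. At 480 min it had 0 reads. ERCC names come before the last name listed there, so an end part-way through the alphabet does not account for this. The 95 barcode columns other than that of the primer the labels name held 6680 reads at 0 min, 5666 at 60 min, 4532 at 120 min, 6905 at 240 min, 3809 at 480 min, 9011 at 600 min and 7044 at 720 min, which is 0.0368% to 0.0572% of the reads in genes. No explanation was tested for either signal. Both drew attention because they exceeded the 3 counts that a count of 0 allows.

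The 480 min table lists 9854 genes, against 16543 or more in the others. It held 49.4% of that library's sense reads. In the other 6 libraries, genes up to the last name it lists hold 49.1% to 50.6% of the reads in their tables, and those tables hold 98.6% of the sense reads. The share is consistent with a table that ends part-way through the alphabet, and values for later genes at 480 min were therefore treated as missing. No biological explanation was tested.

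SPRR2D, S100P, CSTA and KRT81 rose late, by fitted log2 changes of 9.11 ± 0.29, 5.92 ± 0.36, 4.06 ± 0.32 and 2.75 ± 0.23 (SE, edgeR adjusted p = 7.75e-06, 0.000233, 0.000383 and 0.000494). They were grouped, and CSTA and KRT81 chosen, after their values were seen, with no test of a shared function, and other epidermal genes went the other way at single times (log2 ratio to 0 min -1.52 for CNFN at 60 min and -3.23 for FLG2 at 240 min). RNA from epidermal cells would bring abundant keratinocyte transcripts, but at 720 min KRT5 and DSP had 1 count each, against 3741 for SPRR2D, and the 2 such genes with enough counts to test, KRT10 and SFN, had a median fitted change of 0.40. KRT10 was abundant throughout, with 1258 counts at 0 min and 1302 at 720 min. With KRT10 included, a further criterion, keratin counts far below those of SPRR2D, was not met. The 4 genes kept their calls in all 28 combinations of a gene and a left-out time, which cannot tell regulation by the stress response from time in the plate, since the genes were picked for rising and no unlit later library was used. SPRR2D and S100P have no value at 480 min, so leaving out that time removed no value of theirs. A rise linked to illumination is a hypothesis that stays open.

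CYP1A1 had the upward bend of smallest p. Aryl hydrocarbon receptor activity, a candidate explanation, would bend its other targets upward: 2 of the 5 measured did, CYP1B1 by 0.98 ± 0.16 (SE, edgeR adjusted p = 0.00185) and AHRR by 1.25 ± 0.21 (adjusted p = 0.00183). TIPARP had a bend of 2.15 ± 0.73 (adjusted p = 0.101), while ALDH3A1 bent downward by -1.01 ± 0.22 (adjusted p = 0.00589) and NQO1 by -0.46 ± 0.14 (adjusted p = 0.0278). This missed the bound set beforehand, which asked for at least 50% of the targets, by 1 gene. The interval of the share, 5.27% to 85.3% (exact binomial), was added after the count was seen and spans that bound, so 5 genes are too few to decide. Over all 13566 genes tested, 2379 bent upward and 1859 downward.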

How the results depend on the processing

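All alternatives had been fixed before the data were examined. The number of genes with a trend, 930, ranged from 135 to 1481 as each time was left out, and was 1581 with DESeq2; without 600 min 135 of the 902 of these genes still tested kept the call, and with DESeq2 921 of 930 did. The number with a bend, 4238, ranged from 1320 to 4307 as each time was left out, and stayed within 1.5 times under the other alternatives. Of the lists, 11 to 15 were called as each time was left out and 0 with an estimated correlation, where the ISR regulators (mean 1.89, adjusted p = 0.296), amino acid genes (1.63, 0.204) and tRNA synthetases (0.69, 0.317) were no longer called. Fewer libraries leave fewer degrees of freedom. This alone does not account for the spread, since trends numbered 1481 without 0 min and 1145 without 240 min, above 930. The cause was otherwise not tested. The counts of genes at least 2-fold from 0 min stayed within 1.5 times under every alternative run. Other directions turned, each without a call: RPS6 (-0.015) and RPL9 (-0.0021), both near UMI saturation so that this sign carries no information, and the circadian list (0.0042) with UMI counts, COX7C with read counts (0.037), the circadian list after thinning (0.00063) and on the rank time scale (0.16), CLOCK on the log time scale (0.0081), and the bends of TRIB3 (-0.41) and ASNS (-0.052) on the rank time scale. With each time left out, the trends ranged from -0.0499 to 0.37 for RPL9, -0.20 to 0.0329 for COX7C, -0.39 to 0.52 for EIF2AK2, -0.30 to 1.80 for ATF3 and -0.22 to 0.0072 for CLOCK, the TRIB3 bend from -0.0014 to 1.21, and the list means from -0.51 to 1.03 for NF-kB targets, -0.10 to 0.28 for OXPHOS and -0.42 to 0.51 for the circadian clock. The cause was not tested. Of the other values for single genes and lists, 1362 trends, 271 bends and 260 list results were on the same side of the threshold, 226, 10 and 30 fell short of it and 7, 10 and 5 newly passed it. Each time has 1 library, so depth limits low genes and nothing here measures variation between cultures. No paired analysis was possible because each group holds 1 library.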

Other observations

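The gene families tested here were chosen after the first results were seen, and each bound was set before its own result was. Of 15 measured host transcripts of small nucleolar RNAs, which are known targets of nonsense-mediated decay, 7 rose or bent upward and 0 fell or bent downward. GAS5 bent upward by 0.96 ± 0.26 (SE, edgeR adjusted p = 0.0231), SNHG8 by 1.35 ± 0.21 (adjusted p = 0.00144), SNHG15 by 1.28 ± 0.32 (adjusted p = 0.0245) and EPB41L4A-AS1 by 1.68 ± 0.34 (adjusted p = 0.00955), with SNHG7 and TAF1D also called, and SNHG5 rose by 0.75 ± 0.18 (adjusted p = 0.0428). Reduced decay while eIF2 is phosphorylated, the hypothesis, asked for a rise or an upward bend in more than 50% of them, a bound missed by 1 gene. The share of 46.7% has an exact binomial interval of 21.3% to 73.4%, added after the count was seen. This interval spans 50%, so the bound cannot decide. Among 5414 other genes of the 6-library fit, zinc finger (ZNF) genes aside, 1088 rose or bent upward, a smaller share. The 2 shares are not on equal terms. The host transcripts had a median count of 1930, against 282.5 for the other genes, and the shares were not matched on level. GAS5 and EPB41L4A-AS1 were fitted on 7 libraries. The difference in share was not tested and does not by itself identify reduced decay as the cause.

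Zinc finger genes of the ZNF family, many of which encode short-lived transcripts, bent upward in 32% of 444 genes, against 17.2% of 5414 other genes fitted on the 6 complete libraries and 16.3% of others matched on level (odds ratio 2.26, one-sided Fisher's exact p = 3.58e-13 across genes, which are not independent replicates). ZNF317 bent upward by 1.11 ± 0.20 (SE, edgeR adjusted p = 0.00208), ZNF655 by 0.71 ± 0.16 (adjusted p = 0.00615) and ZNF770 by 0.58 ± 0.17 (adjusted p = 0.0225), while ZNF664 had a bend of -0.13 ± 0.14 (adjusted p = 0.484). As a hypothesis, short-lived transcripts may be kept longer while translation is low; half-lives were not measured, and reads shared between family members were not excluded.

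Chance in the order of the libraries was tested by refitting the trend and the curve with the times in random order. For the trend 1 of 100 orders, the real one, gave 930 or more calls, the highest other giving 832, and for the curve 1 of 100 gave 4238 or more, the highest other giving 290. None of the random orders tried gave as many calls as the real one. For the trend, random orders with 832, 728 and 595 calls show that other structure among the libraries also gives many trends. With 1 library per time, this test cannot separate illumination from other changes that follow time.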
